A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

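The series holds 12 single-colour Agilent expression arrays (Cy3) of Saccharomyces cerevisiae, in 4 groups of 3 cultures each. Per the labels, the strains were BY4741 (WT) and BY4741 with CTR1 deleted (Dctr1). The groups were WT with an empty vector (WT_Con), WT over-expressing full-length CTR1 (WT_CTR1), the deletion strain with an empty vector (Dctr1_Con) and the deletion strain over-expressing the truncated construct CTR1 delta-300 (Dctr1_CTR1D300, here CTR1D300). Per the labels, cells pre-grown in SC medium without leucine were brought to an OD600 of 0.6 and grown for 7 h at 30 °C and 180 rpm with 0.02 mM CuCl2, and 0.4 µg of RNA was labelled.

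Per the file headers, the authors' scanner files came from Agilent Feature Extraction 10.7.1.1 for array design 016322, whose annotation names the assembly sacCer1. The processed signal is a background-subtracted and detrended intensity per spot, not scaled between arrays, as deposited. The deposited median spot signal and median local background are raw intensity values, and the deposited flags (other: 0 or 1 per spot) mark spots well above background, saturated spots and outlier spots. The authors' series matrix holds 5202 values per array on the log2 scale, 5191 of them gene probes and 11 of them control probes. Its columns share 1 median of 11.7, so these deposited log2 values were quantile normalised. Each of its columns correlated with the log2 signal of its own scanner file at r of 0.99969 or more across probes. How its probes were chosen is not given in the sources used here.

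Each array has 13048 spots, 536 of them controls, and 6256 gene probes with 2 spots each, which cover 6228 genes. Of these genes, 5740 were named through a RefSeq table of assembly R64 and 488 kept the systematic name printed on the array. Because the array design names another assembly than this table, no coordinates are given and the table served for names only. The median processed signal per array ranged from 1792 to 2999. Between 96.5% and 98.9% of probes per array were well above background, no spot was saturated, and 0 to 3 spots per array carried an outlier flag. The number of arrays limits the precision.

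Before the data were examined, the following was fixed. The log2 processed signal was taken relative to each array's 75th percentile, the 2 spots of a probe were averaged, and the brightest probe stood for each gene. Probes well above background on at least 3 arrays were kept (6155 kept, 101 removed), which left 6127 genes. Group means were fitted to all 12 arrays together with limma 3.58.1 in R 4.3.3, without a block and with 8 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. The 5 comparisons were WT_CTR1 against WT_Con, CTR1D300 against Dctr1_Con, Dctr1_Con against WT_Con, CTR1D300 against WT_CTR1, and the difference between the construct effects (interaction). Of 51 gene lists, 49 had at least 3 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. Errors given with log2 fold changes are standard errors from the limma fit.

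By a rule fixed in advance, the genes named were taken from a pool filled in part from these data. It holds CTR1 and the strain's marker genes, every measured member of the copper uptake, copper detoxification and CTR1-neighbour lists, and the 8 largest rises and falls of the first 3 comparisons (5 for the others) among called genes whose groups did not overlap. It also holds up to 4 called members of each list. HIS3, URA3 and MET17 were not well above background on any array. Genes with near-identical copies (THI5, THI11, THI12 and THI13; CUP1-1 and CUP1-2; RPL41A and RPL41B) may share probe signal and are uncertain as single genes.

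Replicate numbers were checked for pairing before the fits were compared. Same-numbered arrays deviated together from their group means: r across genes was 0.750, 0.692 and 0.342 for WT_CTR1 with WT_Con, 0.679, 0.699 and 0.394 for CTR1D300 with Dctr1_Con, and 0.554, 0.295 and 0.134 for Dctr1_Con with WT_Con. For CTR1D300 with WT_CTR1 it was 0.381, 0.407 and -0.03. The labels give 3 independent experiments. The file headers place replicate 1 of all groups on slide 1, scanned on the earlier of 2 days, the other WT arrays on slide 2 and the other deletion-strain arrays on slide 3.

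In every slide the control arrays lay in the first column and the over-expressing arrays in the second. After the data were seen, the spots of a probe were found to disagree by column. The change in the gap between the 2 spots from one column to the other had a median absolute deviation of 0.24 (log2), against at most 0.06 in 20 draws that balanced the columns. This change exceeded 0.5 for 764 of 6127 genes, against at most 36 in those draws, and exceeded 1 for 139 genes, against at most 5. Fits to the lower-numbered or the higher-numbered spot alone, and calls made with both, were therefore added. Comparisons within a strain carry this column difference, whereas it cancels between strains and in the interaction. A change shared by both constructs cannot be told apart from the column.

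The pipeline was tested on simulated data with 67, 67 and 66 genes seeded at log2 changes of 0.5, 1 and 2. It recovered 58.2%, 92.5% and 100% of them for WT_CTR1 against WT_Con with 4.57% false calls, and 61.2%, 89.6% and 98.5% for CTR1D300 against Dctr1_Con with 8.79% false calls. For Dctr1_Con against WT_Con the shares were 64.2%, 95.5% and 100% with 3.89% false calls, and for CTR1D300 against WT_CTR1 68.7%, 94.0% and 100% with 4.37%. For the interaction they were 37.3%, 82.1% and 100% with 5.81%. The seeded list was called in all 5 comparisons and 0 other lists were. The simulated noise was drawn independently for each gene and array, without inter-gene correlation, replicate pairing or the column difference. How the tests behave under these was therefore not simulated. In the measured data, lists that passed fell from 21 to 4 for WT_CTR1 against WT_Con once the correlation was estimated. For CTR1D300 against Dctr1_Con they fell from 24 to 3, and for Dctr1_Con against WT_Con from 9 to 1. For CTR1D300 against WT_CTR1 and for the interaction they fell from 23 to 5 each.

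The alternatives were quantile normalisation, median centring, background correction by normexp on the median signal, the authors' series matrix values, other probe filters, the mean of a gene's probes, fits to the compared groups alone, a trended robust variance prior, replicate and slide blocks, a 2-fold minimum, and leaving out each array in turn. Leaving out slide 1, a replicate block within each strain, normexp on the median signal and the spot alternatives were added after the data were seen. Control spots and flagged outlier spots were left out of the fits, and a list of plasmid genes and a list of marker genes had too few measured members to be tested.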

Results

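Expression of 6127 yeast genes was compared among 4 groups of 3 cultures grown for 7 h with 0.02 mM CuCl2. The groups were wild type with an empty vector (WT_Con), wild type over-expressing the plasma membrane copper transporter CTR1 (WT_CTR1), a ctr1 deletion strain with an empty vector (Dctr1_Con), and the deletion strain over-expressing a truncated CTR1 (CTR1D300). Within groups, arrays correlated across genes at r of 0.992 to 0.998, and the median SD per gene was 0.10 to 0.12 on the log2 scale. Values are log2 fold changes ± SE with n = 3 arrays per group, and adjusted p values are from limma for genes and from its camera test for gene lists.

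The CTR1 probe (YPR124W) separated the groups. Relative to the array's 75th percentile, its mean log2 signal was -2.50 ± 0.03 (SD, n = 3) in WT_Con and 4.62 ± 0.13 (SD, n = 3) in WT_CTR1. It was not well above background on any array of either deletion-strain group, so it gave no reading of the truncated construct. YPR123C, an open reading frame that overlaps CTR1, was at -3.36 in WT_Con, -1.19 in WT_CTR1, -9.83 in Dctr1_Con and -4.85 in CTR1D300, where it was well above background on all 3 arrays against 1 of 3 in Dctr1_Con.

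**Figure D1:**
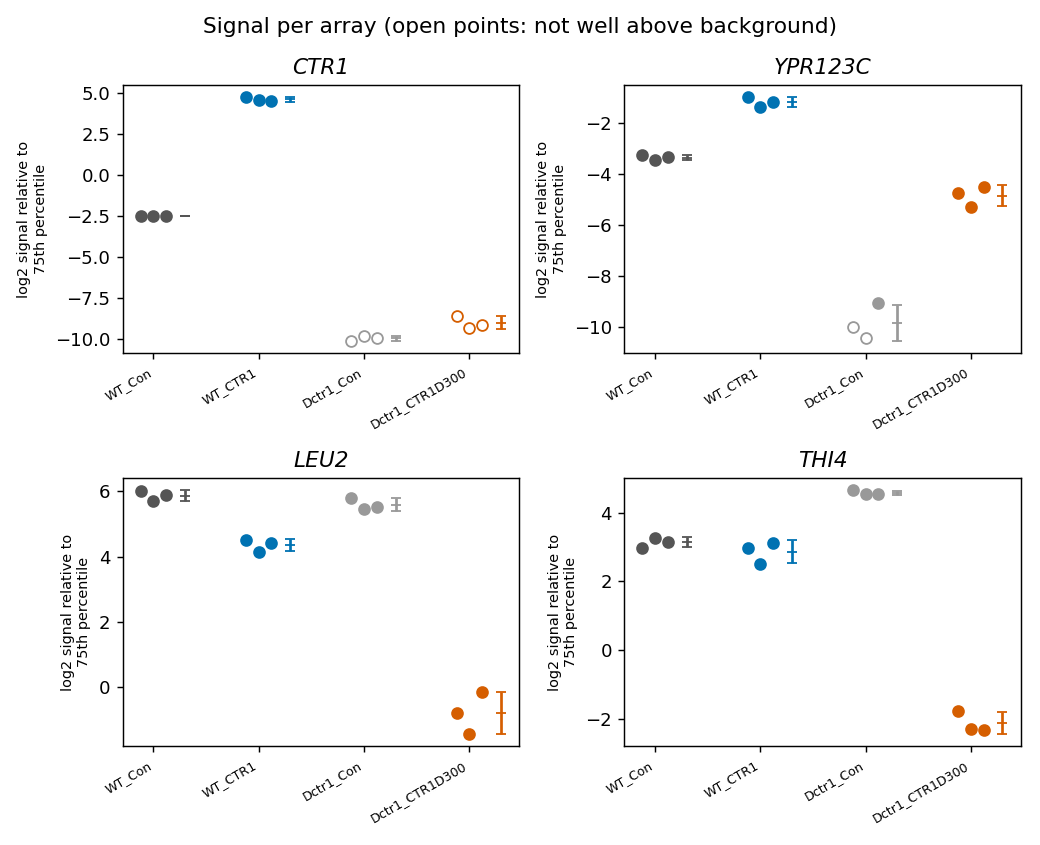
Log2 signal relative to the array's 75th percentile for CTR1, YPR123C, LEU2 and THI4 on each array of the 4 groups, with the group mean and SD beside the points. LEU2 averaged -0.79 with CTR1D300 against 5.59 in Dctr1_Con, and THI4 -2.13 against 4.57.

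The first comparison asked what over-expression of full-length CTR1 changed in wild type. CTR1 rose by 7.12 ± 0.16 (adjusted p = 6.58e-10), and genes of amino acid synthesis fell together. In the branched-chain amino acid list, 13 of 14 members fell over all genes and 14 of 14 when adjusted over the list alone (median -0.78, adjusted p = 6.9e-14, and 0.043 with an estimated correlation). These included LEU1 (-1.59 ± 0.24), ILV3 (-1.28 ± 0.17) and LEU4 (-1.03 ± 0.12). The vitamin B6 genes SNO1 (-2.28 ± 0.40) and SNZ1 (-2.22 ± 0.35) and the acidic amino acid permease gene DIP5 (-2.15 ± 0.23) were among the steepest falls.

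Of 9 arginine synthesis genes 6 fell, and 6 fell and 1 rose when adjusted over the list alone, with ARG7 at -1.12 ± 0.09 (median -0.58, adjusted p = 0.00022, and 0.043 with an estimated correlation). Of 15 aromatic amino acid genes 10 fell (11 adjusted over the list alone), with ARO4 at -0.94 ± 0.09 and ARO3 at -0.88 ± 0.09 (median -0.46, adjusted p = 3.1e-08, and 0.043 with an estimated correlation). Of 6 histidine genes 5 fell (5 adjusted over the list alone), with HIS4 at -0.79 ± 0.10 (adjusted p = 2e-05, but adjusted p = 0.19 with an estimated correlation). Of 17 purine synthesis genes 12 fell (14 adjusted over the list alone; median -0.55, adjusted p = 2e-08, but adjusted p = 0.38 with an estimated correlation). LEU2, a leucine synthesis gene that the BY4741 chromosome lacks, fell by 1.51 on the log2 scale (SE 0.26, adjusted p = 0.00341). LEU2 also fell with CTR1D300 (-6.38), so its fall with CTR1 cannot be told apart from the slide column. Whether the vectors differ in a LEU2 marker was not tested either, so this fall is no clear part of the fall in amino acid synthesis.

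Cell wall genes rose: 8 of 19 were higher and 1 lower (11 and 1 adjusted over the list alone; median 0.30, adjusted p = 0.00068, and 0.043 with an estimated correlation), among them PIR3 (1.31 ± 0.21). Unfolded protein response genes were higher in 8 of 16 cases (13 adjusted over the list alone). These included SIL1 (0.48 ± 0.08) and the oxidative folding genes MPD1 (0.56 ± 0.08) and ERO1 (0.47 ± 0.10). That list passed at adjusted p = 1.4e-06 (adjusted p = 0.21 with an estimated correlation). Of 32 general stress genes 6 rose (9 adjusted over the list alone; median 0.49, adjusted p = 8.1e-05, but adjusted p = 0.67 with an estimated correlation). Other rises were RTA1 (1.83 ± 0.24), HUG1 (1.53 ± 0.22), SPS100 (1.48 ± 0.18) and GRE1 (1.34 ± 0.18). RTA1 also rose with CTR1D300 (1.25, adjusted p = 0.0014), so its rise cannot be told apart from the slide column. Among copper genes, CTR3 was at 0.10 ± 0.08 (adjusted p = 0.49), FRE1 at 0.34 ± 0.15 (adjusted p = 0.166, and 0.0108 with a replicate block), CUP1-1 at -0.21 ± 0.14 (adjusted p = 0.356) and CRS5 at -0.08 ± 0.08 (adjusted p = 0.582). FRE7 was at 0.42 ± 0.12 (adjusted p = 0.0346) but was not called with each spot alone, and IRC7, a member of the copper uptake list, fell (-0.77 ± 0.09, adjusted p = 0.000555). The copper uptake list (2 of 6 higher, CTR1 itself and FRE7, and 1 lower, also when adjusted over the list alone; adjusted p = 0.11) and the copper detoxification list (0 of 4 changed, also when adjusted over the list alone; adjusted p = 0.51) did not pass.

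In all, 813 genes changed, 444 up and 369 down (376 up and 453 down with median centring, 155 up and 217 down with both spots). Of the 813, 68 changed by at least 2-fold, 27 up and 41 down, and the amino acid lists moved alike on both slides (branched-chain median -0.80 on slide 1 and -0.77 on slide 2). The count was 1677 with a replicate block, 1307 with slide as a fixed block, 349 without slide 1 (which ended the calls of LEU2 at -1.51 with adjusted p = 0.063, SNO1 at -1.98 with adjusted p = 0.062 and ERO1 at 0.42 with adjusted p = 0.122) and between 482 and 539 without WT_CTR1 replicate 3 or 1 or without WT_Con replicate 2 or 3. The 2 spots of a probe differed by slide column: 372 genes were called in the same direction with each spot alone, 369 of them among the 813. Of the 813, 98 had spots of opposite sign. RPL41A and RPL41B averaged 2.32 ± 0.18 and 1.68 ± 0.16, but their higher-numbered spots were at -0.30 and -0.41. Apart from FRE7, the genes named above as changed were called with both spots. Both spots of a probe lie on the same array, so a column difference that moved both would pass this check.

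The second comparison asked what the truncated construct changed in the deletion strain. Thiamine and biotin genes fell. THI4, which makes the thiazole of thiamine, fell by 6.70 on the log2 scale (SE 0.18, adjusted p = 1.45e-09), and all 19 thiamine genes fell (19 adjusted over the list alone; median -2.02, adjusted p = 5.3e-14, but adjusted p = 0.054 with an estimated correlation). All 6 biotin genes fell (6 adjusted over the list alone), with BIO5 at -3.92 ± 0.18 and BIO3 at -3.27 ± 0.07 (median -3.11, adjusted p = 3.4e-06, but adjusted p = 0.056 with an estimated correlation). LEU2 fell by 6.38 on the log2 scale (SE 0.26, adjusted p = 2.65e-08).

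Genes of amino acid synthesis rose. All 14 branched-chain genes were higher (14 adjusted over the list alone; median 1.19, adjusted p = 7.8e-09, but adjusted p = 0.056 with an estimated correlation), including OAC1 (1.66 ± 0.13) and BAT1 (1.48 ± 0.12), although LEU2 itself, which this list leaves out, fell. All 9 arginine genes rose (9 adjusted over the list alone), with ORT1 at 1.85 ± 0.07 and ARG4 at 1.58 ± 0.08 (median 1.45, adjusted p = 1.4e-06, and 0.031 with an estimated correlation). Of 15 aromatic genes 14 rose (14 adjusted over the list alone; median 0.88, adjusted p = 2.7e-08, and 0.032 with an estimated correlation), as did all 6 histidine genes (6 adjusted over the list alone; median 1.30, adjusted p = 1.9e-05, but adjusted p = 0.15 with an estimated correlation). Sulfur and methionine genes rose in 25 of 32 cases and fell in 2 (25 and 3 adjusted over the list alone), with the sulfate permease genes SUL1 (3.08 ± 0.49) and SUL2 (1.89 ± 0.12) among them (adjusted p = 5.4e-09, but adjusted p = 0.15 with an estimated correlation). Iron-sulfur cluster assembly genes rose in 15 of 25 cases and fell in 1 (16 and 2 adjusted over the list alone), with ISU2 at 1.74 ± 0.08 and DRE2 at 1.36 ± 0.07 (adjusted p = 1.9e-05, and 0.032 with an estimated correlation).

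Ribosomal protein genes rose in 99 of 138 cases and fell in 1 (104 and 1 adjusted over the list alone; median 0.35, adjusted p = 1.7e-14, but adjusted p = 0.43 with an estimated correlation). Ribosome biogenesis genes rose in 44 of 75 cases (49 adjusted over the list alone; median 0.54, adjusted p = 7.4e-08, but adjusted p = 0.67 with an estimated correlation). General stress genes fell in 23 of 32 cases (23 adjusted over the list alone; median -1.09, adjusted p = 2e-05, but adjusted p = 0.63 with an estimated correlation). Trehalose and glycogen genes fell in 17 of 19 cases (18 adjusted over the list alone), with GLC3 at -2.19 ± 0.33 (list adjusted p = 0.00018, but adjusted p = 0.62 with an estimated correlation). Respiratory chain genes fell in 26 of 40 cases and rose in 1 (27 and 1 adjusted over the list alone; median -0.43, adjusted p = 6.5e-05, but adjusted p = 0.63 with an estimated correlation). Of 23 S phase genes 20 fell (20 adjusted over the list alone; adjusted p = 5.4e-06, but adjusted p = 0.15 with an estimated correlation). OYE3 (3.20 ± 0.13) and PHO89, a sodium-phosphate transporter gene (3.17 ± 0.31), also rose.

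For metals, TIS11 (-2.77 ± 0.17), FIT2 (-1.99 ± 0.26), CCC2 (-1.16 ± 0.08) and the multicopper oxidase gene FET3 (-0.90 ± 0.07) fell. The iron regulon as a list (6 higher and 15 lower of 32, also when adjusted over the list alone; adjusted p = 0.067) did not pass. CTR3 was at -0.31 ± 0.08 (adjusted p = 0.0106, and 0.088 with quantile normalisation) and CRS5 fell by 0.36 on the log2 scale (SE 0.08, adjusted p = 0.00291, and -0.34 with adjusted p = 0.0513 without slide 1). IRC7 rose by 1.26 ± 0.09 and REE1 by 0.95 ± 0.10. CUP1-1 was at -0.45 ± 0.14 and SOD1 at -0.43 ± 0.13, and neither gene was called with each spot alone. The copper uptake list (3 of 6 higher and 1 lower, also when adjusted over the list alone; adjusted p = 0.063), of which the CTR1 probe counted as higher was at background in both groups, and the copper detoxification list (3 of 4 lower, 3 adjusted over the list alone; adjusted p = 0.19) did not pass.

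In all, 3341 genes changed, 1468 up and 1873 down (1697 up and 1653 down with quantile normalisation, 1652 up and 1674 down with median centring), 499 of them by at least 2-fold, and the thiamine median was -2.21 on slide 1 and -2.05 on slide 3. Among all 6127 genes, 2339 were called in the same direction with each spot alone, and 125 of the 3341 had spots of opposite sign.

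**Figure D2:**
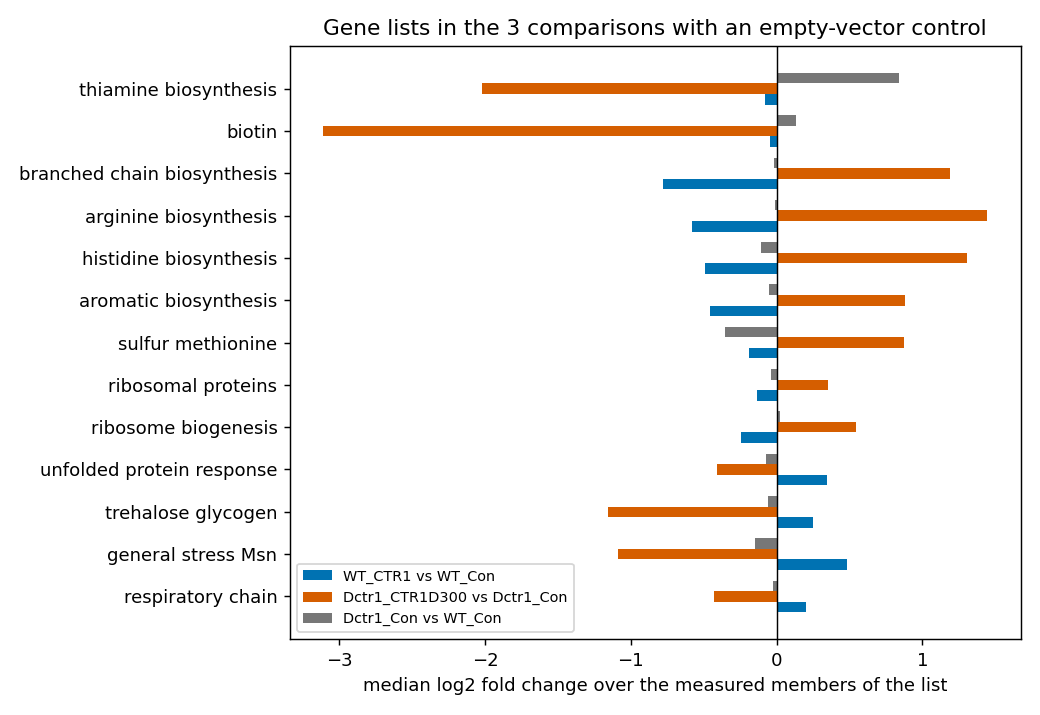
Median log2 fold change over the measured members of 13 gene lists for the 3 comparisons with an empty-vector control, as horizontal bars from 0. Branched-chain amino acid genes stood at -0.78 with CTR1 and at 1.19 with CTR1D300, and thiamine genes at -2.02 with CTR1D300 and 0.84 with the deletion.

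The third comparison asked what the deletion of CTR1 changed. Thiamine genes rose: 15 of 19 were higher (18 adjusted over the list alone; median 0.84, adjusted p = 3.4e-63, and 0.0019 with an estimated correlation). THI5 rose by 1.82 ± 0.13, THI4 by 1.44 ± 0.18 and the thiamine-linked pyruvate decarboxylase gene PDC5 by 1.63 ± 0.13, and without slide 1 the call of THI4 was lost (1.33, adjusted p = 0.0535). The CTR1 probe was at least 111-fold lower, a bound set against background, and YPR123C was well above background on only 1 of 3 Dctr1_Con arrays. The mitochondrially encoded COX3 fell by 1.19 on the log2 scale (SE 0.10, adjusted p = 7.66e-05).

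Of 32 sulfur and methionine genes 2 fell over all genes and 22 when adjusted over the list alone (median -0.35, adjusted p = 2.3e-20, but adjusted p = 0.079 with an estimated correlation). MET2 (-0.83 ± 0.15, adjusted p = 0.0422) and MET3 (-0.72 ± 0.12, adjusted p = 0.027) fell, and without slide 1 they were at -0.72 and -0.59 with adjusted p values of 0.21 and 0.19. Zinc regulon genes had a median of -0.23 with 1 of 21 lower (6 adjusted over the list alone; adjusted p = 3.6e-07, but adjusted p = 0.17 with an estimated correlation). Of 13 mitochondrially encoded genes 1 fell (4 adjusted over the list alone; adjusted p = 3.7e-06, but adjusted p = 0.51 with an estimated correlation). The copper genes CTR3 (-0.05 ± 0.08, adjusted p = 0.953), FRE1 (0.21 ± 0.15, adjusted p = 0.813), CUP1-1 (-0.31 ± 0.14, adjusted p = 0.546) and CRS5 (0.18 ± 0.08, adjusted p = 0.553) did not pass.

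In all, 30 genes changed, 20 up and 10 down, against 525 at an unadjusted p under 0.05, and 99 changed with a replicate block, where the balance turned (36 up and 63 down). Only slide 1 held both strains, and there the thiamine median was 0.73 and the sulfur median -0.42. Elsewhere strain and slide cannot be told apart, and the count fell to 18 without WT_Con replicate 1 or 3 or without Dctr1_Con replicate 3.

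The over-expressing groups were then set against each other, a comparison in which strain and construct differ together. Only slide 1 held both groups, and elsewhere the slide cannot be told apart from strain and construct. Stress genes were lower with CTR1D300 in 29 of 32 cases (29 adjusted over the list alone; median -1.76, adjusted p = 9.4e-07, but adjusted p = 0.55 with an estimated correlation). Ribosome biogenesis genes were higher in 72 of 75 cases (73 adjusted over the list alone; median 0.83, adjusted p = 2.8e-13, but adjusted p = 0.54 with an estimated correlation). All 14 branched-chain genes were higher (14 adjusted over the list alone; median 2.07, adjusted p = 1.3e-11, and 0.032 with an estimated correlation). SNO1 (4.82 ± 0.40), SNZ1 (4.31 ± 0.35) and DIP5 (4.28 ± 0.23) were far higher, while THI4 (-4.99 ± 0.18) and YOR387C (-4.85 ± 0.72) were far lower.

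In all, 3851 genes differed, 1499 up and 2352 down. Among all 6127 genes, 3458 were called in the same direction with each spot alone. The median over all genes was -0.11, and the share of differing genes that were higher was 38.9% here, 50.5% with quantile normalisation, 48.0% with median centring and 49.6% in the authors' series matrix values.

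The last comparison asked whether the constructs acted differently in their strains. Amino acid genes differed: all 14 branched-chain genes (14 adjusted over the list alone; median 2.14, adjusted p = 4.2e-12, and 0.029 with an estimated correlation), 7 of 9 arginine genes (7 adjusted over the list alone; median 1.99, adjusted p = 5.8e-07, and 0.017 with an estimated correlation) and 12 of 15 aromatic genes (12 adjusted over the list alone; median 1.34, adjusted p = 3.5e-10, and 0.017 with an estimated correlation) moved higher with CTR1D300 than with CTR1. Cell wall genes moved lower in 13 of 19 cases (14 adjusted over the list alone; median -0.76, adjusted p = 9.8e-05, and 0.024 with an estimated correlation). All 19 thiamine genes moved lower (19 adjusted over the list alone; median -2.22, adjusted p = 2.3e-13, but adjusted p = 0.051 with an estimated correlation), with THI4 at -6.43 ± 0.25. SNO1 (5.18 ± 0.56) and DIP5 (3.93 ± 0.33) moved higher.

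In all, 2845 genes differed, 1209 up and 1636 down (1411 up and 1357 down with median centring, 1398 up and 1381 down with quantile normalisation). Among all 6127 genes, 2337 were called in the same direction with each spot alone. Across genes, which are not independent replicates, the construct effects correlated at r = -0.29 (Spearman's rho = -0.31), and at -0.29, -0.09 and -0.37 within replicates 1, 2 and 3. Of 577 genes called for both constructs, 63.6% moved in opposite directions: 198 were lower with CTR1 and higher with CTR1D300 (88.4 would be expected from independent lists) and 169 the reverse (136 expected). Another 132 were higher in both (106 expected) and 78 lower in both (113 expected). Spots disagreed by over 0.5 between columns for 56.1% of those higher in both and 30.8% of those lower in both. The share was 14.2% for genes higher with CTR1 and lower with CTR1D300, and 5.6% for the reverse. With the same spot for both constructs r was -0.07 and -0.10, and with different spots -0.37 and -0.38.

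**Figure D3:**
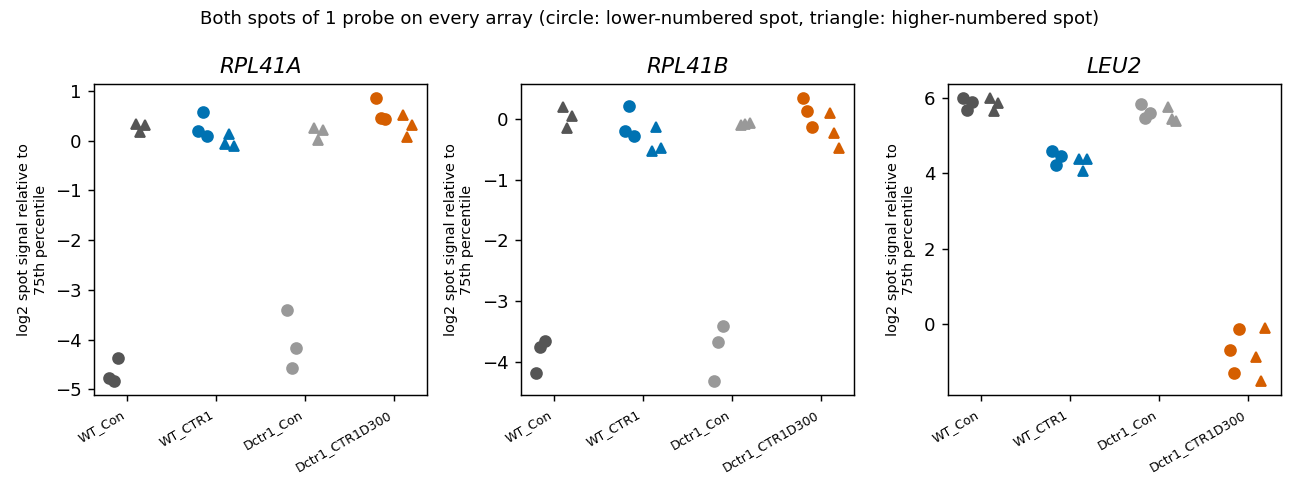
Log2 signal of both spots of the RPL41A, RPL41B and LEU2 probes on each array, circles for the lower-numbered spot and triangles for the higher-numbered spot, by group. The lower-numbered spots of RPL41A and RPL41B stood low on all 6 control arrays, while both spots of LEU2 fell with CTR1D300.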

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

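Of the tests in this part, those of the LEU2 spots, of the strain's marker genes, of the Leu3 targets, of the replicate spread of RPL41A and RPL41B, and of slide and column for the amino acid genes were chosen only after the result was seen.

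The construct effects differed between the strains for 2845 genes by limma's interaction test. Strain labels were exchanged within the control arrays and within the over-expressing arrays, and the real labelling was counted among the 100 compared. Of these 100 labellings, 6 gave as many genes, the real labelling among them, with 3458 the highest other, so this does not exclude chance. All 6 kept the over-expressing groups apart, as 10 of the 100 labellings did, and the highest count among those that mixed them was 0. The counts thus follow a structure of the samples, the separation of the over-expressing groups. Because the control groups differed by only 30 genes, exchanging control labels alone could be expected to give like counts, so the labellings could hardly decide.

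The differences between the construct effects that stood out by this test were, on the log2 scale, 4.07 for SUL1, 3.81 for YGL024W, 5.18 for SNO1, 4.58 for SNZ1 and 3.93 for DIP5, all higher with CTR1D300. They were -4.87 for LEU2, -6.43 for THI4, -4.50 for ISF1 and -4.08 for BIO5. The value for CTR1, -6.16, is no measured size, since its probe was not well above background in either deletion-strain group and the value includes the difference between their background readings.

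For the other comparisons, 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. Every other split also mixes the compared groups, so a real difference between them adds to the spread and lowers the count. The low counts of the other splits therefore do not measure chance. WT_CTR1 against WT_Con gave 813 genes against 1 in the highest other split, CTR1D300 against Dctr1_Con 3341 against 0, Dctr1_Con against WT_Con 30 against 1, and CTR1D300 against WT_CTR1 3851 against 0. In the first 3 of these, where replicate numbers pair the arrays, the splits that part all pairs gave 0 in the highest other.

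With CTR1D300, LEU2 signal fell by 6.38 on the log2 scale. Failed spots are argued against, since the lowest Dctr1_Con spot stood 5.53 above the highest CTR1D300 spot. Arrays of a strain that carries HIS3, URA3 or MET17 are argued against, since these genes gave 0 calls well above background on the CTR1D300 arrays, but another strain that lacks them too is not excluded. Leucine shortage read by Leu3 would raise LEU2, itself a Leu3 target, so it points the wrong way for this fall. That holds only if the measured LEU2 copy, which is not on the chromosome, kept its control by Leu3, and this is not known here. A part of such a shortage in the rise of other genes cannot be told apart from the general rise of amino acid genes. The 9 Leu3 targets other than LEU2 had a median of 1.24 and 30 other amino acid genes 1.20, a difference of 0.0400 (two-sided permutation p = 0.711). A difference between the vectors in their LEU2 marker stays open and was not tested, because the plasmids are not given in the sources used here.

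RPL41A and RPL41B averaged higher with both constructs. The spread of the replicates is argued against, since the lowest same-numbered difference was 1.42. A defect of 1 of the 2 spots is consistent with the data: the lowest change of a single spot was -0.41, and the lower-numbered spots stood low on all 6 control arrays. A test of the slide column through genes of like brightness found 0 with a like rise, but it averaged the spots of each probe, and the column difference sits in single spots, so it decides nothing and the bound set for it in advance was wrong. No biological explanation was tested.

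Of 44 amino acid synthesis genes, 34 fell with CTR1 (median -0.60) and 43 rose with CTR1D300 (median 1.20). No growth measurement was used, and growth state was tested through the mean of ribosome biogenesis genes as a covariate. The medians were then -0.55 and 1.12, with 35 and 43 genes past the threshold. The fit sets the covariate's weight by differences among arrays of the same group, which also carry replicate and slide differences. The result therefore does not decide on growth state. Slide or scan day is argued against, since the smallest medians within a slide were -0.60 and 1.14. The column of the slide is argued against as the whole cause of both movements. It cancels in the difference between the construct effects, which was 1.80. That difference cannot tell how much of the fall with CTR1, or of the rise with CTR1D300, came from the column. A biological effect of the constructs may account for the difference between their effects, as a hypothesis that was not tested. Strain and construct differ together, and growth state and the vectors' markers stay open.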

How the results depend on the processing

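The replicate block within strains, leaving out slide 1, normexp on the median signal (in place of normexp on the mean signal, not run because the files hold no mean signal) and the alternatives by spot were chosen after seeing the data. Of 159 counts and correlations across the alternatives, 137 stayed within 1.5 times or 1 SD and 22 moved. Of 6027 list values 5777 stayed called or stayed not called, 112 gained a call and 138 lost it. Of the 138 losses, 82 came with the estimated inter-gene correlation alone, so the pooled figure understates how far list calls depend on that setting. Of 18788 values of named genes 18036 stayed so, 55 gained a call, 683 lost it and 14 reversed. Values called in neither setting count as unchanged, even where their sign changed. The named genes were also picked in part from these data as called genes, so these shares do not measure robustness.

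For WT_CTR1 against WT_Con (813) the count was 1677 with a replicate block, 2296 with a replicate block within strain, 1307 with slide as a fixed block, 1338 with slide as a random block, 68 with a 2-fold minimum, 349 without slide 1, 1353 with the lower-numbered spot and 372 with both spots. Leaving out 1 array gave 482 (without WT_CTR1 replicate 3) to 1134 (without WT_CTR1 replicate 2), with 537 and 539 without WT_Con replicate 2 or 3 and 518 without WT_CTR1 replicate 1. The 2-fold minimum gave 499 for CTR1D300 against Dctr1_Con, 10 for Dctr1_Con against WT_Con, 780 for CTR1D300 against WT_CTR1 and 752 for the interaction. With a replicate block, Dctr1_Con against WT_Con gave 99 genes (36 up and 63 down).

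Leaving out 1 array gave 2803 to 3242 for CTR1D300 against Dctr1_Con, 18 (without WT_Con replicate 1 or 3 or Dctr1_Con replicate 3) to 35 for Dctr1_Con against WT_Con, 3365 to 3900 for CTR1D300 against WT_CTR1 and 2269 to 3196 for the interaction. The correlation of the construct effects ranged from -0.38 to -0.21 and was -0.0703 with the lower-numbered and -0.10 with the higher-numbered spot. For Dctr1_Con against WT_Con, 66.7% of changed genes were higher, 77.4% with quantile normalisation and 76.7% in the series matrix values.

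With normexp, DAN1 (0.0015, adjusted p = 0.996) and YPR123C (-0.0350, adjusted p = 0.924) in the interaction lost the difference called in the main fit and ended near 0 with the other sign. In the main fit YPR123C rose by 2.17 with CTR1 and by 4.98 with CTR1D300, so the loss was large. DAN1 was near background with CTR1D300 and YPR123C in Dctr1_Con, but whether this accounts for the loss was not tested. Reversed with the series matrix values CUP1-2 (0.14) with CTR1. Reversed with the lower-numbered spot were NCP1 (-0.0914) and MRPL49 (-0.10) with CTR1 and BSD2 (0.11) with CTR1D300. Reversed with the higher-numbered spot were RPL41B (-0.41), RPL41A (-0.30), HEM12 (-0.21), ZRT1 (-0.17), MRPL23 (-0.0013) and RPT4 (-0.0356) with CTR1, and RPL41B (-0.12) and MRPL23 (-0.17) with CTR1D300. Only CUP1-2 passed the test in its new direction (adjusted p = 0.0476). The cause was tested only for RPL41A and RPL41B, as a defect of 1 of the 2 spots. Apart from FRE1, YPR127W and CUP1-2, and SOD1 and CRS5 in the interaction, which gained a call, the replicate block changed no call of a named gene. Among lists it brought in general stress for the deletion (adjusted p = 0.018) and heat shock for CTR1D300 (adjusted p = 0.018), lost NAD synthesis for CTR1D300 (adjusted p = 0.052), and changed no other list. Signal over background limits CTR1 in the deletion strain and the 101 probes removed as dim.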

Other observations

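With CTR1D300 further gene groups moved in the deletion strain. Mitosis genes fell in 14 of 18 cases and rose in 1 (15 and 1 adjusted over the list alone; median -0.57, adjusted p = 0.0046, but adjusted p = 0.15 with an estimated correlation). Cell wall genes fell in 11 of 19 cases and rose in 1 (11 and 1 adjusted over the list alone; median -0.57, adjusted p = 0.0013, but adjusted p = 0.054 with an estimated correlation), with SED1 at -1.26 ± 0.09 (SE, n = 3). Proteasome genes fell in 19 of 32 cases and rose in 1 (19 and 1 adjusted over the list alone; median -0.22, adjusted p = 0.0043, but adjusted p = 0.43 with an estimated correlation). Unfolded protein response genes fell in 11 of 16 cases (11 adjusted over the list alone; median -0.41, adjusted p = 0.0063, but adjusted p = 0.43 with an estimated correlation), with the chaperone gene KAR2 at -0.89 ± 0.06. Kynurenine pathway genes of NAD synthesis fell in 7 of 10 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.03, 0.052 with a replicate block, and adjusted p = 0.22 with an estimated correlation), with BNA2 at -2.73 ± 0.13.

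Lists of mating type, pheromone response and meiosis genes were also tested. With CTR1D300, the list of a-specific genes (1 of 7 higher and 1 lower, also when adjusted over the list alone; adjusted p = 0.97) and that of alpha-specific genes (2 of 6 higher and 2 lower, also when adjusted over the list alone; adjusted p = 0.66) did not pass, although MF(ALPHA)1 fell by 2.52 on the log2 scale (SE 0.14). Meiosis and sporulation genes fell in 13 of 19 cases and rose in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.0039, but 0.73 in the authors' series matrix values, and adjusted p = 0.43 with an estimated correlation). With CTR1, meiosis and sporulation genes rose in 6 of 19 cases and fell in 1 (7 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.0024, and adjusted p = 0.41 with an estimated correlation), and the call of meiosis_sporulation was lost with the lower-numbered spot alone (adjusted p = 0.121) and in the authors' series matrix values (adjusted p = 0.0745). The alpha-specific list, with 1 of 6 higher (1 adjusted over the list alone; median 0.25), passed narrowly at adjusted p = 0.0499 (adjusted p = 0.28 with an estimated correlation) and was lost with the lower-numbered spot alone (adjusted p = 0.236). The a-specific list with CTR1 (2 of 7 lower, 3 adjusted over the list alone, median -0.10, adjusted p = 0.13) did not pass. STE2 (-0.70 ± 0.09) and MFA1 (-0.81 ± 0.16, and -0.80 with adjusted p = 0.0501 without slide 1) nevertheless fell. STE2 also fell with CTR1D300 (-0.30, adjusted p = 0.0191), so its fall cannot be told apart from the slide column. Pheromone response genes fell with CTR1 in 4 of 17 cases and rose in 1 (6 and 1 adjusted over the list alone; median -0.17, adjusted p = 0.0075, but adjusted p = 0.41 with an estimated correlation), and the call was lost with the lower-numbered spot alone (adjusted p = 0.059).

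The values per spot were chosen for study after the result was seen. Fold changes from the lower-numbered and the higher-numbered spots correlated across genes at 0.418 for WT_CTR1 against WT_Con, 0.828 for CTR1D300 against Dctr1_Con, 0.825 for Dctr1_Con against WT_Con, 0.990 for CTR1D300 against WT_CTR1 and 0.979 for the interaction. Of the 813 genes called with CTR1, 214 had a gap between spots that differed by over 0.5 between the columns, as had 423 of the 3341 called with CTR1D300.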
